A study of Mus musculus with 2 samples.

How the data were processed

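H3K27ac ChIP-seq was done on midbrain tissue of newborn mice in 2 biological replicates, each a pool of both sexes. The replicate numbers and the tissue come from the sample labels, which name biological replicates with separate biosamples, so both samples form 1 group with n = 2. The labels also give both the same donor identifier, so that the pools are independent rests on the labels alone. The first pool is from 15 mice, per the labels.

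Per the descriptions deposited with the files, the authors aligned the reads to mm10 and called peaks on replicate 1, on replicate 2 and on both together, and derived a replicated list from these 3 lists. Each call also used 2 further files whose role is not stated. The aligner, the peak caller and the rule behind the replicated list are not given in the sources used here. For each peak the authors deposited a display score scaled within the list, a fold enrichment (a ratio over the peak's background), and a p-value and a q-value, both as −log10. The deposited position of each peak's summit was not used. The lowest −log10 p was 2.00 to 2.05 in the 4 lists, so the lists begin at a lenient threshold, and 87.1% (replicate 2) to 99.7% (replicated list) of the peaks had a q-value under 0.05. No read counts are in the lists. The depth of each replicate is therefore unknown, and the ratio of 1.33 between the replicates' peak counts may not be read as a difference in biology. The fold enrichment was used to describe, rank and filter peaks within a list, and was never tested between lists.

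Coordinates are mm10, 1-based. The reference sequence and annotation were GRCm38.p6 and GENCODE M21, which is the same assembly, and no peak ended beyond the length of its reference chromosome. Start sites for location and motifs were those of all annotated genes, and gene lists used all transcripts of 21938 protein-coding genes. Xist, as a non-coding gene, was reported without a test. Of the 278 list entries none lacked a match by symbol. A promoter peak is a peak overlapping the window of 1000 bp on each side of a start site. For genomic location, each peak was placed by its midpoint, in the order promoter, exon, intron and intergenic sequence, and compared with 100 circular shifts of the peaks along each chromosome. Where several peaks overlapped a promoter, the highest fold was taken.

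Each of 24 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The stratified version was an exact test of the number of marked members given their CpG classes. The classes were set by the highest observed-to-expected CpG ratio within 500 bp of any start site, with bounds at 0.4 and 0.6. Domains were made by joining replicated peaks 12.5 kb or less apart and ranked by the sum of width times fold, and the 500 highest were compared with start sites up to 10000 bp away. A distal peak had its midpoint over 1000 bp from every start site, so a wide one may still overlap a promoter window. For motifs, the central 400 bp of distal peaks were searched on both strands for 17 consensus sequences and compared with windows 10000 bp downstream that met no peak of the pooled list or of either replicate. Windows with unknown bases were left out, and matched windows were drawn at random from sequence outside peaks and promoters. The paired windows were compared by the exact McNemar test, two-sided. Of 24224 distal peaks 20698 had such a window, and 20526 could be matched to a window of similar GC content (bins of 2 percentage points) and CpG count. Overlap between replicates required 1 bp, and intervals of shares are Clopper-Pearson at 95%.

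The gene lists, the motifs, the tests, the number of domains and the rule for named genes were fixed before the data were examined. The use of CpG classes was fixed as well, but their bounds and window were written after the lists had been opened, and first used after the tests without CpG classes had been seen. The rule took, in each list, up to 4 members with the highest fold and up to 2 members without a replicated promoter peak in list order, the 20 highest domains with their protein-coding genes, and the 10 promoters with the highest fold. Genes named as domain members of a list, non-coding genes in domains, Pecam1, Fev, Htr1a, Hoxa2 and Hoxb5 in the replicates' lists, the distances to 5' ends, and all genes of the closing section outside this rule were chosen after their values had been seen. So were Aldh1l1, Aqp4 and S100b. Alternatives fixed beforehand were the pooled list, the stronger 50% of peaks by p-value, promoter windows of 500 bp and 2500 bp, each replicate's own list, CpG classes, joining at 5000 bp, ranking by width, 250 and 1000 domains, a motif window of 200 bp, and the reversed consensus. Basic transcripts, peaks present in both replicates' lists and matched motif windows were added after the data had been seen. Peaks on unplaced and unlocalized contigs were left out of location, domains and motifs.

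The procedures were tested on simulated data. Of 100 simulated lists of 12 genes marked at 95%, 87% were called, and of 100 lists marked at the genome's share 1% were called. Overlap calls equalled a direct count for 300 of 300 peaks. A sequence planted in 3% of windows was recovered as a difference of 3 percentage points, and 0 of 10 sequences that were not planted had a p under 0.05. Genes were marked at random and window bases drawn evenly, so these checks do not cover calls that arise from CpG or GC content. Only higher marking in lists of 12 was simulated, with adjustment over 200 lists. How often lower calls or calls in smaller lists would be found was not checked. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1 indexed the reference.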

Results

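Acetylation of histone H3 at lysine 27 (H3K27ac), a chromatin mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the mouse midbrain on the day of birth (postnatal day 0). The 2 biological replicates were separate pools of midbrains from males and females, the first from 15 mice and the second from a number of mice that the labels do not give. Whether the pools shared litters is not stated, and the labels give both pools the same donor identifier. Both belong to 1 group, so the design holds no contrast between conditions, and the comparisons are between genes, between genomic regions and between the replicates. The data are 4 lists of peaks on the mm10 build. Replicate 1 had 90501 peaks and replicate 2 had 68053, and 84641 peaks were called on both replicates together (the pooled list). The authors' replicated list held 40931 peaks with a median width of 584 bp and covered 35.2 Mb, or 1.29% of the genome. Read counts are not part of the peak lists, so the sequencing depth of each replicate is unknown. Fold enrichment is the authors' value for each peak within its own list, and values from different lists are given side by side without a test.

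Every pan-neuronal gene tested carried H3K27ac at its promoter. All 15 pan-neuronal genes had a replicated peak within 1000 bp of an annotated start site, against 54.6% of all other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 24 lists, adjusted p = 9.63e-04). The highest fold enrichments in this list were 35.6 at Mapt, which encodes the microtubule protein tau, 27.4 at the neurofilament gene Ina, 27.3 at Stmn2 and 26.9 at Map2. The Mapt peak spans chromosome 11:104230752-104234849 across the 5' end of the gene, and its fold was 33.3 in the list of replicate 1 and 25.4 in that of replicate 2. All 15 promoters also had a peak in each replicate's own list. The fold is 1 value per peak, and where in a wide peak it arose was not examined. The fold given for a gene is that of its highest peak at any annotated start site. For 23 of 114 list entries with a peak, this peak lay over 1000 bp from the 5' end of the gene, and 11 of these had no replicated peak within 1000 bp of that end. The Map2 peak lay 144 kb from the 5' end, which had a peak of its own. Because 86.1% of promoters rich in CpG dinucleotides carried a peak, against 51.1% of intermediate and 7.34% of CpG-poor promoters, each list was also tested within CpG classes, and there the pan-neuronal list kept an adjusted p of 9.61e-04. Genes are not independent replicates, so these tests describe the libraries at hand.

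Glutamatergic and GABAergic neuron genes were acetylated at most of their promoters. Of 12 glutamatergic genes 11 had a promoter peak (adjusted p = 0.020 by Fisher's exact test). They included Slc17a6, the vesicular glutamate transporter VGLUT2, at 19.3-fold, Tcf7l2 at 17.8-fold, Tfap2d at 13.1-fold and Ebf3 at 12.4-fold, and the member without a peak was Slc17a7, which encodes VGLUT1. Of 12 GABAergic genes 10 had one, which missed the threshold (adjusted p = 0.089 by the same exact test). Gad1 and Gad2, the enzymes that make GABA, reached 15.5-fold and 12.02-fold, and the transcription factor genes Gata3 and Tal1 reached 11.9-fold and 11.8-fold, while Tal2 and Helt had no peak. The glutamatergic call was lost within CpG classes (exact test, adjusted p = 0.83), and both lists consist mainly of CpG-rich promoters, 11 of 12 in each. From these classes 9.98 of 12 genes were expected to have a peak in each list, which left little room for a higher count.

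Most dopaminergic, cholinergic and serotonergic neuron genes had no replicated promoter peak. Of 12 dopaminergic neuron genes 2 had a replicated promoter peak, Ddc (aromatic L-amino acid decarboxylase) at 6.28-fold and Ret at 4.83-fold, fewer than among other genes (adjusted p = 0.028 by Fisher's exact test, and 8.72e-04 within CpG classes). The Ddc peak lay 75.5 kb from the 5' end of the gene, near the start site of a shorter annotated transcript, and with basic transcripts 1 of 12 genes had a peak (exact test, adjusted p = 0.0070). Th, the rate-limiting enzyme of dopamine synthesis, and the dopamine transporter gene Slc6a3 had no promoter peak in any of the 4 lists. By the same exact test this call was lost in the pooled list, where 4 of 12 genes had a peak (adjusted p = 0.13), in the list of replicate 1 alone (adjusted p = 0.12), and with a window of 2500 bp (adjusted p = 0.061). None of 8 cholinergic and motor neuron genes had a promoter peak, Chat and Slc18a3 among them (adjusted p = 0.0090 by the exact test). None of 5 serotonergic genes had one, including Tph2 and Slc6a4 (adjusted p = 0.031 by the exact test), but Fev had a peak in the list of replicate 2 and Htr1a in that of replicate 1. In each of these lists the call was lost (exact test, adjusted p = 0.22 in replicate 2 and 0.21 in replicate 1).

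Progenitor and astrocyte genes mostly had a promoter peak, and 6 of 12 oligodendrocyte lineage genes did. Of 13 neural progenitor genes 12 had a promoter peak (adjusted p = 0.020 by Fisher's exact test). In the replicated list they were led by the RNA-binding protein gene Msi1 at 27.7-fold and the Notch target Hes5 at 21.6-fold. Sox2 and Fabp7 followed at 10.6-fold each, and Neurog2 had none. The place of Hes5 was not kept in the replicates' own lists. There its fold was 7.34 (replicate 1) and 7.16 (replicate 2), below the 9.61 and 8.84 of Sox2. The replicated Hes5 peak, chromosome 4:154960931-154965323, ran past the 3' end of the gene, so its 21.6-fold need not lie at the promoter. The progenitor call was lost within CpG classes, where 10.4 of 13 genes were expected to have a peak (exact test, adjusted p = 0.61). Of 10 astrocyte genes 9 had a peak (adjusted p = 0.038 by the exact test, and 2.36e-04 within CpG classes). The glutamate transporter gene Slc1a2 reached 15.0-fold, Aldoc 9.14-fold, Sparcl1 7.42-fold and Gja1 5.56-fold, while Gfap lacked a replicated peak. Aldh1l1 had no promoter peak in the list of replicate 2, and S100b none in that of replicate 1. The Aldh1l1 and Aqp4 peaks lay 64.0 kb and 7.24 kb from 5' ends without a replicated peak. With peaks in both replicates' lists 7 of 10 genes had one, and the call was lost (exact test, adjusted p = 0.41). Among the stronger 50% of replicated peaks 5 of 10 astrocyte genes had one, and the call was lost (exact test, adjusted p = 1). It was also lost in each replicate's own list, where the share moved little, with 8 of 10 genes in replicate 2 and 9 of 10 in replicate 1 (exact test, adjusted p = 0.24 and 0.086). Of all protein-coding genes 55.8% and 58.5% had a promoter peak in these lists, against 54.6% in the replicated list. Of 12 oligodendrocyte lineage genes 6 had a peak (adjusted p = 0.78 by the exact test). Olig1, Cnp, Olig2 and Nkx2-2 carried 6.86-fold, 6.17-fold, 5.08-fold and 4.92-fold enrichment, and Sox10 and Cspg4 had no replicated peak.

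Of the 5 lists of immune, vascular, meningeal, blood and choroid plexus cells, the microglia, meningeal and erythroid lists had fewer promoter peaks than other genes, and the endothelial and choroid plexus lists missed the threshold. Of 11 microglia genes 1 had a promoter peak, Csf1r at 3.30-fold (adjusted p = 0.013 by Fisher's exact test), and Cx3cr1 and P2ry12 had no replicated peak. Of 9 meningeal fibroblast genes Foxc1 alone had one, at 6.10-fold (adjusted p = 0.026 by the exact test), and the collagen genes Col1a1 and Col1a2 had no replicated peak. The list of replicate 1 and the pooled list each held peaks at 4 of these 9 promoters (exact test, adjusted p = 0.60 for each). Of 9 erythroid genes Gypa alone had one, at 4.69-fold (adjusted p = 0.026 by the exact test), and the beta-globin genes Hbb-bs and Hbb-bt had none. Of 11 endothelial and mural genes 3 had a peak, Kdr at 4.35-fold, Cldn5 at 4.32-fold and Pdgfrb at 4.16-fold, and the difference from other genes missed the threshold (adjusted p = 0.089 by the exact test). The list of replicate 1 had peaks at 7 of these genes, that of replicate 2 at 5 and the pooled list at 6, with Pecam1 in both replicates, although Pecam1 and Cdh5 lacked a replicated peak. Of 7 choroid plexus and ependyma genes Foxj1, a regulator of motile cilia, had a peak of 8.43-fold, and Ttr and Folr1 had none (adjusted p = 0.066 by the exact test). The microglia and erythroid promoters were mostly poor in CpG, and within CpG classes both calls were lost (exact test, adjusted p = 1 for each). There 1.24 of 11 and 1.54 of 9 genes were expected to have a peak, which left little room for a lower count.

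Among regional identity genes, promoter peaks were most frequent in the midbrain list and absent from the Hox clusters, a difference between lists that was not tested. Of 11 midbrain genes 7 had a promoter peak, which did not differ from other genes (adjusted p = 0.78 by Fisher's exact test). From their CpG classes 9.12 would be expected, and this lower count missed the threshold (exact test within classes, adjusted p = 0.21). En2 and En1, the engrailed genes of the midbrain and anterior hindbrain, reached 15.1-fold and 11.2-fold, and Otx2 and Meis2 reached 11.9-fold and 11.6-fold, while Pax2 and Pax5 had no replicated peak. Of 12 forebrain genes 3 had one, Lhx2 at 15.7-fold, Emx2 at 7.88-fold and Neurod6 at 5.08-fold, and Foxg1 and Emx1 had none. The forebrain list missed the threshold (adjusted p = 0.061 by the exact test) and passed it within CpG classes (adjusted p = 2.36e-04). Of 8 hindbrain and cerebellum genes Mafb alone had a replicated peak, at 8.09-fold, and Egr2 and Gbx2 had no replicated peak (adjusted p = 0.038 by the exact test). This call was lost in each replicate's own list, where 2 of 8 genes had a peak (exact test, adjusted p = 0.20 in replicate 2 and 0.11 in replicate 1). None of the 39 Hox genes, which pattern the hindbrain and spinal cord, had a replicated promoter peak (adjusted p = 9.88e-13 by the exact test). Hoxa1 had none in either replicate, and in the list of replicate 2 Hoxa2 had a peak of 3.50-fold and Hoxb5 one of 3.25-fold. Hox genes lie in clusters, so their promoters are even less independent than those of other lists. Hoxa2, Hoxb1 and Hoxb2 are also members of the hindbrain and cerebellum list, so the calls of these lists are not separate results.

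All housekeeping and immediate early genes tested had a promoter peak, and 1 gene each of the liver, muscle and germline lists did. All 15 housekeeping genes had a promoter peak (adjusted p = 9.63e-04 by Fisher's exact test), with 57.9-fold at Actb, 40.7-fold at Ywhaz, 34.8-fold at Polr2a and 32.5-fold at Ppia. All 10 immediate early genes, which respond to activity and stress, had one (adjusted p = 0.011 by the exact test), with 19.6-fold at Dusp1 (52.6 kb from the 5' end of the annotated gene, which also had a peak), 13.5-fold at Jun, 9.69-fold at Egr1 and 7.11-fold at Arc. All housekeeping promoters were rich in CpG, and within CpG classes neither list passed the threshold (exact test, adjusted p = 0.40 for housekeeping and 0.35 for immediate early genes). From these classes 12.9 of 15 and 8.26 of 10 genes were expected to have a peak. Every member had one, so this test could not have called either list higher. In replicate 2 alone 9 of the 10 immediate early genes had a peak, and the call was lost (exact test, adjusted p = 0.076). Of 10 liver genes 1 had a peak, Apoa1 at 6.10-fold (adjusted p = 0.019 by the exact test), and Alb and Afp had no replicated peak. The Apoa1 peak lay 897 bp from the nearest start site and 1038 bp from the 5' end of the gene. With the 500 bp window and with basic transcripts 0% of the liver genes had a peak. Of 12 heart and skeletal muscle genes 1 had a peak, the myosin heavy chain gene Myh7 at 12.4-fold (adjusted p = 0.0090 by the exact test), and Myh6 and Tnnt2 had none. Of 10 germline and pluripotency genes 1 had a peak, Dazl at 6.10-fold (adjusted p = 0.019 by the exact test), and Pou5f1 and Nanog had none. The liver and muscle calls were lost within CpG classes (exact test, adjusted p = 1 and 0.27). There 1.17 of 10 and 2.89 of 12 genes were expected to have a peak, which left little room for a lower count. Of the 4 protein-coding Y-linked genes 3 had a peak, Uty at 5.33-fold, Kdm5d at 5.08-fold and Ddx3y at 4.32-fold, and Eif2s3y had none (adjusted p = 0.69 by the exact test). Xist, the non-coding RNA of the inactive X chromosome, had a promoter peak of 7.27-fold, with 8.40 in the list of replicate 1 and 4.41 in that of replicate 2.

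**Figure D1:**
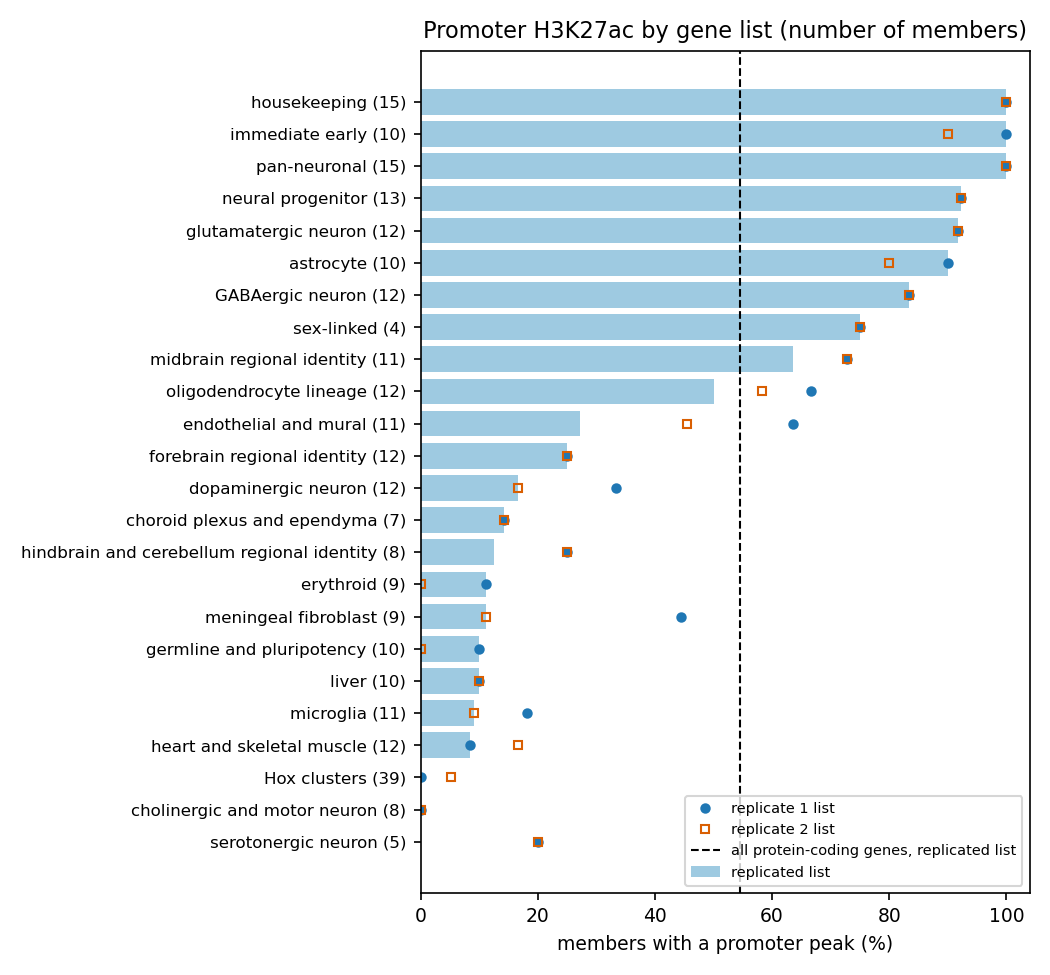
Percent of each gene list's members with an H3K27ac peak within 1000 bp of a start site, on the horizontal axis, with the number of members in brackets. Bars show the replicated list, filled circles the list of replicate 1 and open squares that of replicate 2, and the dashed line marks the 54.6% of all protein-coding genes; pan-neuronal and housekeeping genes stand at 100% in all lists drawn, and cholinergic and motor neuron genes at 0.

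The promoter with the highest fold enrichment was that of Klf7, a zinc finger transcription factor gene, at 62.3-fold over chromosome 1:64117691-64123371, and its fold was 59.2 in the list of replicate 1 and 43.2 in that of replicate 2. It was followed by the beta-actin gene Actb at 57.9-fold, Arrdc3 at 57.3-fold and the chromatin regulator gene Kmt2e at 56.3-fold. Zc3h6 and the predicted gene Gm10762 shared 1 peak of 55.4-fold, and Rhob, Sp3, Cirbp and Gabpb1 had between 53.1-fold and 49.97-fold. Peaks with their midpoint within 1000 bp of a start site had a median fold of 8.13 and a median width of 888 bp (16699 peaks). The 24224 peaks with a midpoint farther away had 4.26 and 478 bp.

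The highest acetylated domains held Cstad, Tnrc18 and Zfhx3 start sites and, in several cases, no protein-coding start site. Joining replicated peaks up to 12.5 kb apart gave 20524 domains, and the 500 with the highest sum of width times fold had a median length of 22.7 kb, against 1.36 kb for all domains. They held 9.57% of the peaks and 22.5% of the summed width times fold. The highest domain spanned chromosome 2:30591171-30726489 and held the start site of Cstad. The second, chromosome 13:83713552-83752036, held no protein-coding start site. It lay over the long non-coding RNA gene C130071C03Rik and the microRNA gene Mir9-2, and the nearest protein-coding start site was that of Mef2c, 60664 bp away. All 3 genes of the neuronal microRNA miR-124 lay in domains among the 20 highest, Mir124a-1 at rank 8, Mir124a-2 at rank 9 and Mir124a-3 at rank 18, and Mir125b-1 lay in the domain of rank 11; these non-coding genes were picked out after their values had been seen. Ranks 3 to 7 held Tnrc18, Zfhx3, Zmynd8, the alpha-tubulin genes Tuba1a and Tuba1b with Gm49450, and Thra and Nr1d1 with Casc3, Med24 and Msl1. Rank 10 held Cirbp with Midn, Cbarp, Atp5d, Efna2 and 1600002K03Rik. Rank 12 held Zfp532, rank 14 Lrrc4b with Aspdh, Emc10, Fam71e1 and Josd2, and rank 15 Irf2bpl, which was also nearest to the domain of rank 13. Rank 16 held Ptms, Mlf2 and Lag3, rank 17 the POU-domain gene Pou3f3, rank 19 Nnat, Blcap and Src, and rank 20 Rhof and Setd1b. Where a domain held no protein-coding start site, the nearest was Kif13b for rank 8, Cypt12 for rank 9, Sorl1 for rank 11 and Ythdf1 for rank 18. Of the 500 domains, 426 overlapped one of the 500 highest of replicate 1, 425 one of replicate 2, and 385 both.

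**Figure D2:**
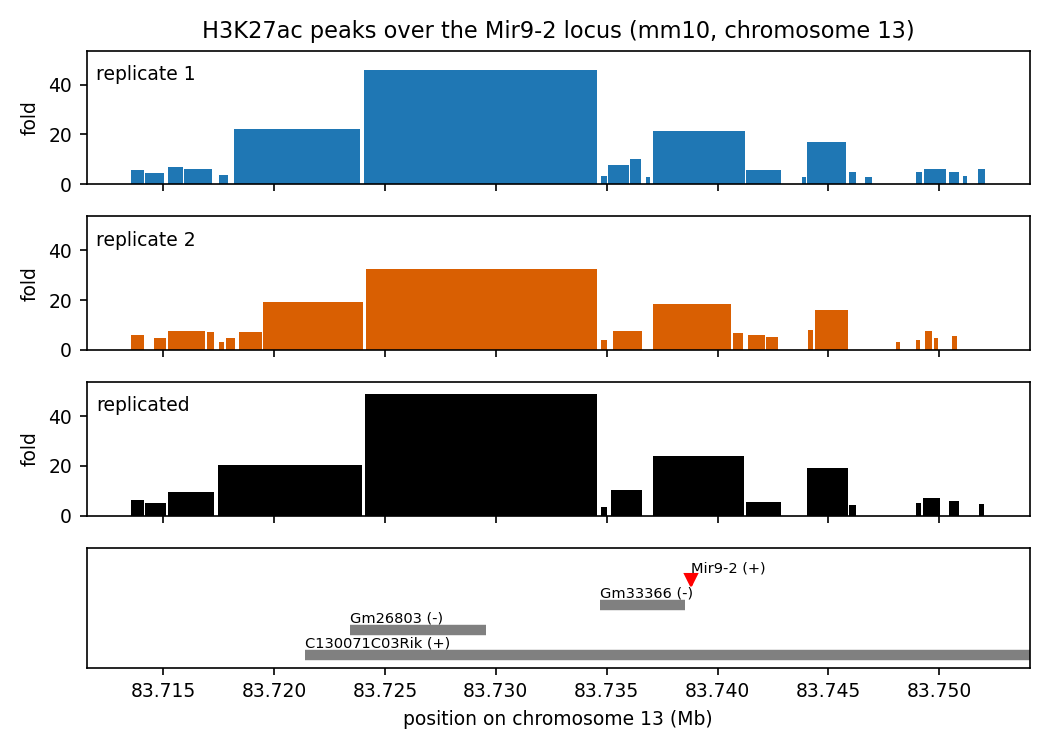
H3K27ac peaks over the second highest domain on chromosome 13 (mm10; horizontal axis in Mb), drawn at their positions with the authors' fold enrichment as height, for replicate 1, replicate 2 and the replicated list. The lowest panel shows the annotated non-coding genes with their strand, and the red triangle marks Mir9-2. The widest and highest peak, of 48.8-fold in the replicated list, lies upstream of it in each list drawn.

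Of all protein-coding genes 4.67% had a start site in or within 10000 bp of the 500 highest domains, and 3 lists were above other genes past the threshold. Housekeeping genes did so with 6 of 15, namely Actb, Eef1a1, Hsp90ab1, Polr2a, Ubc and Ywhaz (Fisher's exact test, two-sided, adjusted p = 8.51e-04). Neural progenitor genes did so with Hes5, Msi1, Notch1 and Sox2, 4 of 13 (exact test, adjusted p = 0.029), and pan-neuronal genes with Map2, Mapt, Stmn2 and Tubb3, 4 of 15 (adjusted p = 0.034). The GABAergic list had 3 of 12, Gad1, Gata3 and Lhx5, and the glutamatergic list had 3 of 12, Slc17a6, Tcf7l2 and Tfap2d (adjusted p = 0.078 for each by the same exact test). The midbrain list had Otx2 and Meis2, 2 of 11 (exact test, adjusted p = 0.36), and no other list passed the threshold. The domain test was not run within CpG classes, where the housekeeping and progenitor promoter calls were lost. The domain calls also moved with the ranking. By total peak width the GABAergic and glutamatergic lists passed (exact test, adjusted p = 2.91e-07 and 1.09e-04) and the housekeeping and pan-neuronal lists did not (adjusted p = 0.13 and 1), and in each replicate's own list the progenitor and pan-neuronal calls were lost (adjusted p = 0.14 to 0.16 and 0.19 to 0.67).

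Promoters held a far larger share of the peaks than chance placement gave. Of 40923 replicated peaks on the assembled chromosomes, 40.8% had their midpoint within 1000 bp of a start site, against a mean of 6.24% in 100 circular shifts of the peaks along their chromosomes and a highest value of 6.82%. Intergenic sequence held 19.1%, against 51.1% in the shifts. Exons outside promoters held 3.76% against 3.34%, and introns held 36.3% against 39.3%. Each of these shares lay outside the range of all 100 shifts. Over the replicates' own lists the promoter share was 30.5% ± 5.50 (SD, n = 2) and the intron share 43.7% ± 3.83 (SD, n = 2). The intron share lay above the mean of its shifts in the pooled list (46.3%), in replicate 1 (46.4%) and in replicate 2 (41.0%, inside the range of the shifts), so its direction depended on the list. The exon share fell under the mean of its shifts among the stronger 50% of replicated peaks (2.77%) and with a promoter window of 2500 bp (2.42%, inside the range of the shifts).

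Peaks with their midpoint away from promoters were enriched in binding sequences of RFX, NFI and ASCL1-type factors. In 20698 distal peaks the central 400 bp held the RFX sequence GTTGCCATG in 1.84% of windows, against 0.531% of windows 10000 bp downstream, a ratio of 3.45 (exact McNemar test, two-sided, adjusted over 17 motifs, adjusted p = 3.29e-35). The NFI palindrome, bound by factors active in glia and maturing neurons, was found in 0.546% against 0.232% (ratio 2.35, exact test, adjusted p = 1.36e-06). The E-box CAGCTGC, of the type bound by the proneural factor ASCL1, was found in 15.5% against 8.09% (ratio 1.91, exact test, adjusted p = 8.52e-121). Peak windows had a mean GC content of 49.4% and the downstream windows 45.0%. Against windows matched on GC content and CpG count, an alternative chosen after the data had been seen, these 3 ratios were 4.20, 1.45 and 1.43 (exact test, adjusted p = 2.69e-42, 0.029 and 1.47e-44). The higher share of NRF1 and ETS sites and the lower share of OTX-PITX and GATA sites against the downstream windows (ratios 7.67, 1.58, 0.774 and 0.846, exact test, adjusted p = 2.99e-04, 0.015, 8.92e-25 and 3.91e-04) were not kept with matched windows (ratios 1.35, 0.918, 0.957 and 1.01, adjusted p = 0.52, 0.69, 0.15 and 0.91). With matched windows the LHX-type homeodomain, MEF2, POU octamer and SOX sequences were more frequent (ratios 1.53, 1.81, 1.30 and 1.12) and the CREB sequence less frequent (ratio 0.597, exact test, adjusted p = 0.0013), none of which passed the threshold against the downstream windows. Peaks are not independent replicates, and a consensus match is not evidence of binding.

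**Figure D3:**
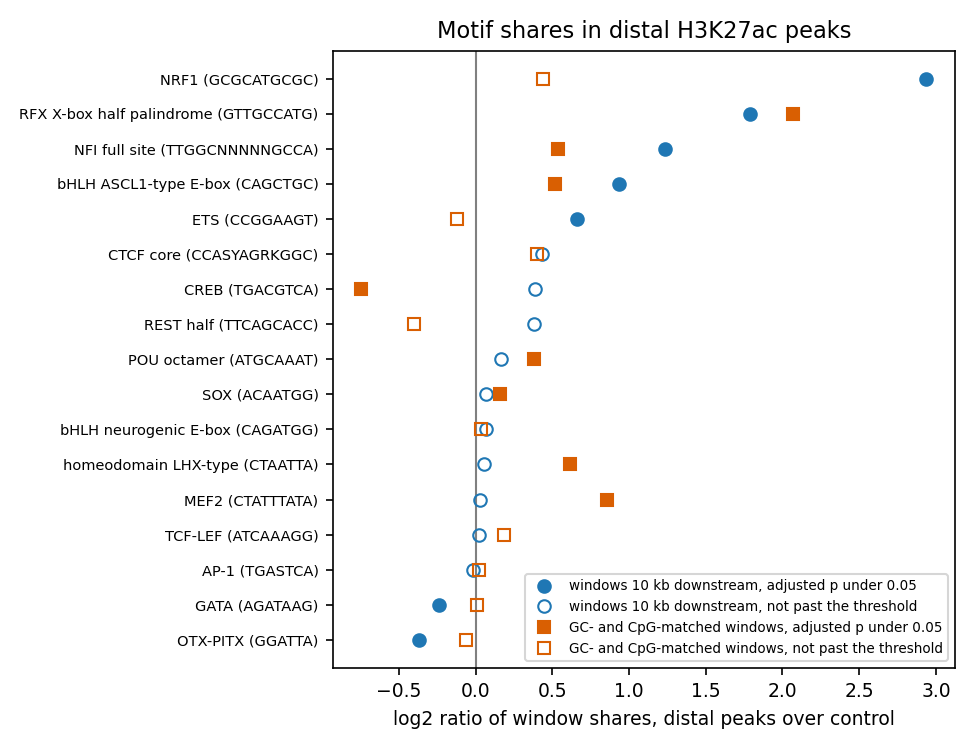
Log2 ratio of the share of windows holding each consensus sequence, distal H3K27ac peaks over control windows, on the horizontal axis. Circles compare with windows 10 kb downstream and squares with windows matched on GC content and CpG count, and filled symbols have an adjusted p under 0.05; the RFX, NFI and ASCL1-type sequences are filled and right of 0 in both.

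The strong peaks were shared by the replicates and the weak peaks often were not. Of the 90501 peaks of replicate 1, 39031 (43.1%, 95% Clopper-Pearson interval 42.8 to 43.5) overlapped a peak of replicate 2 by at least 1 bp, against at most 2.57% in 100 circular shifts. Of the 68053 peaks of replicate 2, 45042 (66.2%, interval 65.8 to 66.5) overlapped a peak of replicate 1, against at most 3.46%. These intervals treat peaks as independent draws and cover counting error only. Among the 10% of each list with the lowest fold the overlap was 15.6% in replicate 1 and 39.8% in replicate 2, and among the 10% with the highest fold it was 99.99% and 100%. Across the 34903 replicated peaks that met a peak in both lists, the fold values of the replicates correlated with a Spearman rho of 0.78, across peaks that are not independent. Every replicated peak had the coordinates of a pooled peak, and 48.4% of the pooled peaks were kept. The share kept was 9.45% among the 10% of lowest fold and 100% among the 10% of highest fold. Of the replicated peaks, 34903 (85.3%) overlapped a peak in both replicates' own lists, 4636 in replicate 1 alone, 1324 in replicate 2 alone and 68 in neither.

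**Figure D4:**
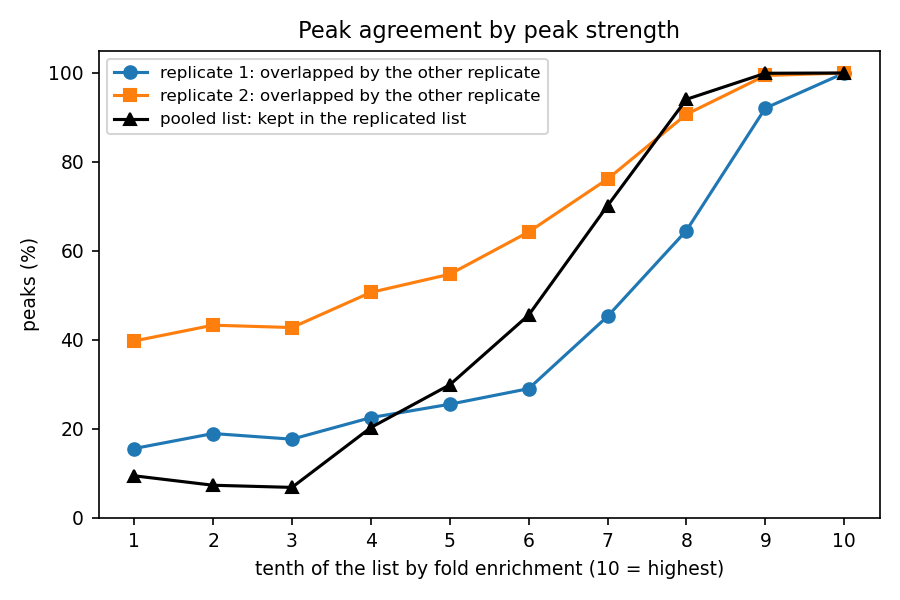
Percent of peaks, on the vertical axis, in 10 equal parts of each list ordered by the authors' fold enrichment, on the horizontal axis (10 is the highest). Circles and squares show the peaks of each replicate overlapped by the other, and triangles the pooled peaks kept in the replicated list, which go from 9.45% in the lowest part to 100% in the highest.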

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

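The tests of X dosage, the CpG test of X-linked genes, the wider window and the neighbouring start sites were chosen after the patterns they bear on had been seen, as was the test of gene number on the X, and for X dosage and gene number the measured result had been seen too; only the CpG test of gene lists was planned beforehand.

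Data outside the comparisons held signal on unplaced and unlocalized contigs. The replicated list had 8 peaks there, with a highest fold of 25.8, and the pooled list had 11, replicate 1 had 12 and replicate 2 had 9. No control library was analysed here.

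The X chromosome carried fewer peaks than any autosome, with 4.44 replicated peaks per Mb against 12.5 to 26.6 on single autosomes, and 1.45 distal peaks per Mb against 9.74 on the autosomes together. Of 948 X-linked protein-coding genes 39.3% had a replicated promoter peak, against 55.7% of autosomal genes (Fisher's exact test, two-sided, p = 4.61e-23), with 43.0% and 38.7% on the X in the replicates' own lists. The CpG content of X-linked promoters accounts for most of this gap, since 41.9% would be expected from their CpG classes, but not for the whole of it (exact test within classes, p = 0.020). A candidate explanation for the rest is the lower X dosage in a pool of males and females, but the values cannot decide it. Marked CpG-rich promoters had median folds of 9.40 on the X and 12.9 on autosomes, a ratio of 0.728 (95% bootstrap interval 0.660 to 0.800). Silencing of 1 X in females could lower it too, and fold is taken over a background that dosage may also lower. A lower number of genes does not account for the whole distal gap, with 0.262 distal peaks per protein-coding gene on the X against 0.692 to 1.99 on single autosomes, and dosage stays open there: scaling the fold of autosomal distal peaks by that ratio, and leaving out those under a guessed floor, left 4.03 per Mb, still above the X density; mappability and silencing of 1 X in females were not tested.

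Dopaminergic neuron genes mostly lacked a promoter peak in the tissue that holds these neurons. The tables argue against CpG content as the whole cause, since within CpG classes 7.27 of 12 genes would be expected to have a peak and 2 did (exact test, unadjusted p = 2.18e-04). Acetylation placed outside the promoter window cannot be told apart from a lack of acetylation: 66.7% of the genes had a replicated peak within 50 kb (95% Clopper-Pearson interval 34.9 to 90.1), against 75.7% of other genes (Fisher's exact test, two-sided, p = 0.50). The interval holds the share of other genes, and Th, Slc6a3, Foxa1 and Lmx1a had no replicated peak in that range. A small share of dopaminergic cells in the dissected tissue may also keep their signal under the peak threshold, and no cell shares were available to test it.

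Single genes of unrelated tissues had a replicated promoter peak, namely Apoa1, Myh7, Dazl and Gypa. The Apoa1 peak lay 897 bp from the nearest start site of the gene and was not counted with the 500 bp window. Of the 4 peaks 0 overlapped the start-site window of another annotated gene, so they are not promoter peaks of a neighbouring gene. Whether they are distal elements of a neighbouring gene was not tested. Apoa1, Dazl and Gypa had a promoter peak in replicate 1 and none in replicate 2, and Myh7 had one in both, of 11.4-fold and 11.1-fold. No biological explanation was tested.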

How the results depend on the processing

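Basic transcripts, peaks in both replicates' lists and matched motif windows were chosen after the data had been seen. No paired analysis was possible because the samples form 1 group. Leaving out a replicate could not be run for the replicate overlap, which needs both, and for the other results it means the other replicate's own list. The overlap of replicates stayed above all shifts (31.9% to 78.8%). The promoter share stayed above its own shifts, from 26.6% in the list of replicate 1 to 61.2% among the stronger 50% of replicated peaks. The share of pooled peaks kept was 48.4% by either definition, which could not differ because every replicated peak equals a pooled interval. The calls of the pan-neuronal, cholinergic, Hox and germline lists held under all 9 alternatives for promoters, with adjusted p up to 0.0030, 0.021, 4.29e-10 and 0.043. Unknown depth limits every count of weak peaks, and small lists limit the tests; where a call changed, the cause was not tested. Of 24 lists, 6 were called higher and 11 lower, against 3 and 9 with the stronger 50% of peaks, 2 and 8 within CpG classes, and 4 and 11 with peaks in both lists. Within CpG classes, lists expected to have peaks at nearly all or nearly none of their promoters had little room for a call. For domains 3 lists were called, against 5 with joining at 5000 bp, and 2 and 1 without replicate 1 and 2. Of the alternatives for promoter lists, 170 values kept their side of the threshold and direction, 34 lost the call, 4 gained one and 8 changed direction. For domains these counts were 114, 9, 10 and 11, and for motifs 32, 7, 14 and 14.

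For location, the intron share lay above the mean of its shifts in the pooled list (46.3%) and without either replicate (41.0% to 46.4%), and inside their range with a 500 bp window (40.0%). The exon share lay under the mean of its shifts among the stronger 50% of peaks (2.77%) and with the 2500 bp window (2.42%).

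For promoter lists, adjusted p values that changed side follow. In the pooled list they were 0.13 for dopaminergic, 0.21 for serotonergic and 0.60 for meningeal genes. Among the stronger 50% of peaks, GABAergic (0.043) and endothelial (0.0047) passed, while glutamatergic (0.13), serotonergic (0.11), progenitor (0.21), astrocyte (1), meningeal (0.072), hindbrain (0.11) and immediate early genes (0.25) were lost. The 500 bp window lost glutamatergic genes (0.061), and the 2500 bp window lost dopaminergic (0.061), astrocyte (0.067), microglia (0.084) and muscle genes (0.061). With peaks in both replicates' lists, glutamatergic (0.062) and astrocyte genes (0.41) were lost. Within CpG classes, forebrain passed (2.36e-04) and glutamatergic (0.83), progenitor (0.61), microglia (1), erythroid (1), immediate early (0.35), housekeeping (0.40), liver (1) and muscle genes (0.27) were lost. Without one replicate or the other, ranges were 0.21 to 0.22 for serotonergic, 0.086 to 0.24 for astrocyte, 0.11 to 0.20 for hindbrain, 0.019 to 0.076 for immediate early, 0.018 to 0.12 for dopaminergic, 0.026 to 0.60 for meningeal and 0.042 to 0.076 for choroid plexus genes. Without a call in either setting, oligodendrocyte genes changed direction in the pooled list (0.77), with the 2500 bp window (0.59) and without either replicate (0.80 to 1). So did endothelial genes without replicate 2 (range without either replicate 0.60 to 1), midbrain genes among the stronger 50% (1) and within CpG classes (0.21), and sex-linked genes within CpG classes (0.64).

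For domains, adjusted p for GABAergic and glutamatergic genes was 0.0029 and 0.0029 with joining at 5000 bp, 2.91e-07 and 1.09e-04 ranked by width, 0.021 and 0.021 for 250 domains, and 0.0014 and 0.011 for 1000. Ranked by width, midbrain genes passed (0.0082), and pan-neuronal (1) and housekeeping genes (0.13) were lost. With 250 domains pan-neuronal (1) and progenitor genes (0.18) were lost, and with 1000 domains progenitor genes (0.084). Without either replicate, ranges were 0.19 to 0.67 for pan-neuronal, 0.14 to 0.16 for progenitor and 0.025 to 0.16 for GABAergic genes. Without a call in either setting, direction changed with joining at 5000 bp for muscle genes (1), ranked by width for astrocyte (1), immediate early (0.050, above the threshold) and muscle genes (1), and with 250 domains for forebrain (1) and muscle genes (1). It also changed with 1000 domains for oligodendrocyte (1), microglia (1) and immediate early genes (0.17), and without replicate 1 for forebrain and immediate early genes (1 for both lists without either replicate).

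For motifs, 5 were called higher and 2 lower, against 1 lower in the central 200 bp, in the stronger 50% and with matched windows, 7 higher with matched windows, and 13 higher against the reversed consensus. Ratios that changed side follow. In the central 200 bp the neurogenic E-box passed (1.11), GATA (0.877) and ETS (1.5) were lost, and SOX (0.991) and LHX-type (0.936) changed direction. In the stronger 50% of distal peaks POU passed (1.32), GATA (0.884) and NRF1 (3.33) were lost, and LHX-type (0.990), MEF2 (0.836) and TCF-LEF (0.876) changed direction. With matched windows SOX (1.12), LHX-type (1.53), MEF2 (1.81) and POU (1.30) passed, OTX-PITX (0.957) and NRF1 (1.35) were lost, and GATA (1.01), ETS (0.918), CREB (0.597), AP-1 (1.013) and REST (0.757) changed direction. Against the reversed consensus SOX (1.85), the neurogenic E-box (4.34), LHX-type (1.34), MEF2 (1.42), CTCF (85.0), POU (12.5), TCF-LEF (1.64) and REST (4.35) passed, GATA (0.970) was lost, and AP-1 (1.097), OTX-PITX (1.03), ETS (0.243) and CREB (0.242) changed direction. Reversal creates CpGs in the RFX, NFI, ASCL1-type, CTCF, POU and REST sequences and removes the CpG from those of ETS and CREB. Their ratios therefore mix CpG content with the motif, and this control cannot separate them. For NRF1 the reversed sequence, which holds more CpGs than the consensus, occurred in no window. No ratio could be given for it, and its call is among the 13.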

Other observations

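All tests here were chosen after the highest domains had been seen, and so were the genes named.

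Brain microRNA genes recurred among the highest acetylated domains beyond those named above. Mir9-1 lay in the domain of rank 21, and Mirlet7b and Mirlet7c-2 lay in that of rank 25. Mir9-3 lay in or within 10000 bp of the domain of rank 37, Mir219a-1 of that of rank 270 and Mir125b-2 of that of rank 374. All 3 genes of miR-9, a microRNA of neural progenitors and neurons, and all 3 genes of miR-124 were thus in or near the 500 highest domains. The long non-coding RNA gene Malat1 lay in the domain of rank 24, the beta-tubulin gene Tubb2b in that of rank 23 and the clustered protocadherin genes Pcdhgc3, Pcdhgc4 and Pcdhgc5 in that of rank 26. Of 2202 annotated microRNA genes, 110 (4.996%) lay in or within 10000 bp of these 500 domains.

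The hypothesis that brain microRNA loci in general lie near such domains was tested on a list of brain microRNAs and a list of microRNAs of other tissues, written after the genes of the 25 highest domains had been looked at. Of 19 brain loci 10 lay near the 500 highest domains, against 0 of 17 loci of other tissues, but the brain list was written knowing 7 of these 10, so this difference is not independent evidence (Fisher's exact test, two-sided, p = 4.40e-04). Outside the 25 highest domains, 3 of 12 brain loci lay near one, and the test missed the threshold (Fisher's exact test, two-sided, p = 0.060). Among them Mir9-3 and Mir125b-2 belong to families already seen in the 25 highest domains, so this version is not independent of that look either. By the same exact test, counting genes in place of loci gave p = 2.03e-05 for all and p = 0.031 outside the 25 highest domains, but neighbouring microRNA genes are not separate loci. Of these 4 versions the locus count outside the 25 highest domains was taken as the deciding one, after the count of all genes had been seen, and it leaves the hypothesis open. Mir128-1, Mir137 and Mir132, also expressed in neurons, were not near any of the 500 domains, and Mir290 of the other tissues was not found in the annotation.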
